A study of Mus musculus with 6 samples.

How the data were processed

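Bulk RNA of 6 mouse tumours was measured, 3 grown from control cells (sgNT) and 3 from cells that had received a CRISPR guide against Uhrf1 (sgUhrf1). The deposited unit is the count: whole numbers of read pairs per annotated feature, not normalized, 1 table per tumour. Per the submitters' processing notes, reads were trimmed with fastp, aligned with STAR and counted with featureCounts, and the genome build was GRCm38. Per the file headers, the counter was featureCounts 2.0.1, run on paired reads over exons grouped by gene name, with chimeric pairs left out, no strand setting, and the GENCODE M26 primary annotation. The headers also show that alignments had been quality filtered before counting; the filter and the versions of fastp and STAR are not given in the sources used here.

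GENCODE M26 carries coordinates of the GRCm39 build, while the notes give GRCm38 for the alignments. This was tested on the files with the GENCODE M21 annotation of GRCm38. Of 50118 row names shared by both annotations, 1455 (2.90%) had the same start, and the median distance between starts was 133071 bp. The 34106 rows whose listed intervals touch no M21 exon held 1.09% of the 35176944 counts. Among rows with a protein-coding name, the median total over the 6 tumours was 0 counts for the 8871 rows over no M21 exon and 154 counts for the 12501 rows over at least 1 M21 gene. The rows named Eef1a1 and Tpt1 held 0 counts, and the row named Rplp0 held 3, although these genes are abundant in nearly every cell. The reads therefore lie at GRCm38 positions, and a row name is in most cases not the name of the gene whose reads it holds.

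Each row was renamed by position. A row was given a gene where its listed intervals, used as they stand and not converted, cover at least 50 bp of exons of a single M21 gene, small RNA genes set aside. This named 13437 rows, holding 40.3% of the counts; 2340 kept their own name and 11097 took another. A further 4952 rows cover exons of several genes and hold 57.9% of the counts; they stayed in all fits and are reported only as shared rows. Where several rows named 1 gene, the row with most counts stood for it. Renaming was checked on pairs of rows that name the same gene. Over 878 genes, the log2 fold changes of both rows correlated with a Pearson r of 0.739 across genes. It was 0.128 for 4501 neighbouring rows that name different genes and at most 0.123 in 1000 shuffles. The Spearman correlation of the pairs was lower, at 0.597, and both rows had the same sign in 68.2% of the genes. Genes are not independent replicates, so these values only describe the naming. Most renamed rows cover a part of the gene's exons, without strand, so reads from antisense genes, introns or close copies inside the same intervals are not separated. Some genes reported below have rows near the 50 bp minimum. Among them, those of Tgfbi, Bax, Nr4a1, E2f1 and Xdh covered 57, 58, 68, 89 and 93 bp. Only 16 ribosomal protein genes were named by position, in 22 rows. Those rows held a median of 194.5 counts over the 6 tumours, and 6 held under 60. The 94 rows that carry such names in the files held a median of 7, and 66 held under 60. The counts of a renamed row therefore need not give the full level of its gene.

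Rows were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, the default filterByExpr filter by group (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment over the 10503 rows that passed; the threshold was an adjusted p of 0.05. Standard errors of log2 fold changes come from the same test. CPM values are counts per 1000000 TMM-scaled counts, given as mean ± SD over 3 tumours. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01, over lists with at least 3 tested members; camera with an estimated correlation and the rotation test fry were run beside it. The test design, the 31 gene lists and the rule for named genes were chosen before the data were examined; the renaming by position was chosen afterwards. The rule names a fixed set of core genes whatever their values, the 10 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups (1786 genes qualified; symbols of predicted genes, pseudogenes and receptor segments were set aside), and up to 4 members past the threshold for each list described, or up to 2 as values where none passed. The result for 1 core gene is not reported here.

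Total counts ran from 5462555 to 6375069 per tumour. A floor of 3 counts, the upper limit that a count of 0 allows, equals 0.445 to 0.660 TMM-scaled CPM per tumour; folds against a group without counts are lower bounds against 3 counts over the whole group, and where a group held 1 to 3 counts the ratio of counts is given with its exact 95% binomial interval. Floors and intervals cover counting error only. The fit was tested on simulated data for sgUhrf1 against sgNT with 3 tumours each, over 10282 rows with 200 changed: 86.9% of rows changed 4-fold and 15.1% of rows changed 2-fold were recovered, and 4.76% of calls were false. All simulated rows had 1 common dispersion (0.0917) and were drawn independently. Real rows differ in dispersion and can vary together, so the false share need not hold for the real calls. The labels number the tumours as biological replicates but do not tie a number to an animal, litter or day across groups; the p-values measure the spread between these tumours. All 3 tumours of a group come from 1 stable cell line as far as the labels say, so the guide and any other difference between both lines cannot be told apart.

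Alternatives were DESeq2 1.42.0, limma-voom, a robust fit, median-of-ratios factors, library totals, no filter, a stricter filter, the replicate number as a block, immunoglobulin and T cell receptor rows left out, a minimum fold of 2, and each tumour left out in turn. Alternatives added after seeing the data were the deposited row names as gene names, shared rows counted for lists, at least 200 bp of overlap, counts summed per gene, mitochondrial and ribosomal RNA rows left out, and the tumours with most muscle reads left out. Library totals moved the median log2 fold change of all rows by -0.16 relative to TMM, and all other scalings moved it by less than 0.1.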

Results

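The study measured RNA in tumours of LG1233-OVA, a mouse lung cancer line that carries the model antigen ovalbumin. Stable lines made with a non-targeting guide (sgNT) or a guide against Uhrf1 (sgUhrf1), which encodes a chromatin protein known for maintaining DNA methylation, were injected under the skin of female C57BL/6 mice at 1000000 cells each. Tumours were collected on day 27, 3 per group. The series title names MHC class I and anti-tumour immunity, so the single comparison, sgUhrf1 against sgNT, asks how the RNA of whole tumours, cancer and host cells together, differed. Each tumour gave between 5462555 and 6375069 counts over 16051 to 18771 detected rows. Genes are named by the GRCm38 exons at the positions counted, because the row names in the files belong to another build. The row listed as H2-K1, for example, lies over the end of Tap2, and the reads of H2-K1 stand under Angptl4.

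**Figure D1:**
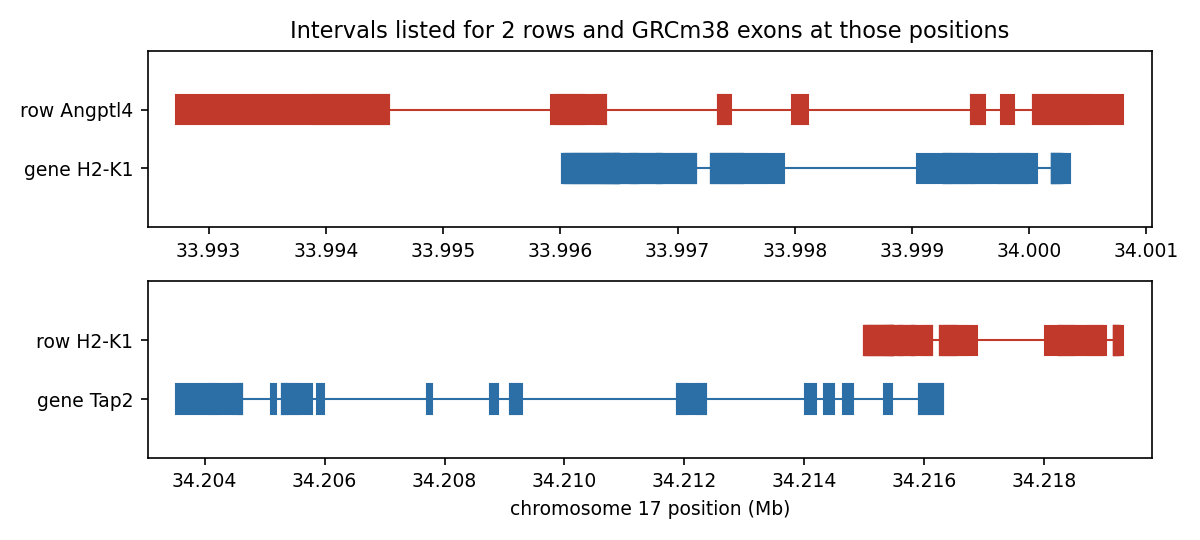
Intervals that the files list for the rows Angptl4 and H2-K1 (red) and GRCm38 exons of H2-K1 and Tap2 at the same place (blue), along chromosome 17 in Mb; thin lines join the exons of a row or gene. The row Angptl4 covers 897 bp of H2-K1 exons, and the row H2-K1 covers 418 bp of Tap2 exons.

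The targeted gene, Uhrf1 (chromosome 17, 56303321 to 56323486, plus strand), stood at 122 ± 21 CPM (SD, n = 3) in sgNT tumours and 94.7 ± 24.5 CPM (SD, n = 3) in sgUhrf1 tumours. Its main row, covering 690 bp of exon, held 841, 917 and 554 counts in the sgNT tumours and 685, 460 and 409 in the sgUhrf1 tumours. The log2 fold change was -0.37 ± 0.23 (SE), with an edgeR adjusted p of 0.227, and the ranges of both groups overlapped. A second row, listed as Stap2 and described after its values were seen, covers 238 bp of exon nearer the 5′ end of Uhrf1. It held 76, 133 and 51 counts in the sgNT tumours and 39, 29 and 36 in the sgUhrf1 tumours, or 12.0, 19.7 and 9.04 CPM against 6.90, 4.60 and 7.92 CPM, with no overlap between groups. Its log2 fold change was -1.08 ± 0.39 (unadjusted p = 0.0212, adjusted p = 0.0524). Over the refits it lay between -1.31 and -0.73, with an adjusted p from 0.0250 to 0.343. It passed the threshold in DESeq2 (adjusted p = 0.0382) and without sgNT replicate 3 (0.0451), among others, and not in limma-voom (0.0574). Dnmt1, the maintenance DNA methyltransferase that Uhrf1 protein recruits, had a log2 fold change of -0.46 ± 0.26 (adjusted p = 0.196). The labels do not say where the guide cuts, a frameshift can leave the transcript in place, and host cells keep an intact gene, so this level does not check the labels.

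Between the groups, 2121 rows were higher and 2066 were lower in sgUhrf1 tumours, 39.9% of the 10503 tested. Of the 4578 tested genes named by position, 945 were higher and 985 were lower. Several of the largest rises were in genes known from gut epithelium, such as Muc3, Spink4 and Lypd8. Among the 10 largest, Lypd8 was at least 724-fold higher, the serine protease gene Prss32 at least 580-fold, the mucin genes Muc3 and Muc3a at least 497-fold and 322-fold, the nucleoside transporter gene Slc28a3 at least 161-fold, the receptor phosphatase gene Ptprh at least 141-fold, the receptor gene Adgrg7 at least 112-fold and the olfactory receptor gene Olfr1189 at least 95.2-fold, all against sgNT groups with 0 counts. Oit1 went from 0.540 ± 0.248 to 495 ± 121 CPM, a log2 fold change of 9.80 ± 0.38 (SE), and Spink4 from 0.201 ± 0.225 to 190 ± 147 CPM, a change of 9.67 ± 0.97. Adjusted p-values of these 10 genes lay between 2.75e-06 and 0.00109. Muc3 and Muc3a are near copies, so reads may be split between them. The rows of Lypd8, Prss32, Ptprh and Adgrg7 covered only 121, 169, 106 and 157 bp of exon, and those of the other genes among these 10 at least 254 bp.

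The 10 largest falls included the imprinted gene Peg10 (chromosome 6, 4747306 to 4760517, plus strand), at 185 ± 56.9 CPM in sgNT and 4.64 ± 1.82 CPM in sgUhrf1 tumours, a log2 fold change of -5.33 ± 0.37 (SE, n = 3 per group, edgeR adjusted p = 0.000103). The ubiquitin ligase gene Hecw1 fell by 6.25 ± 0.58 on the log2 scale, the heparan sulfate sulfotransferase gene Hs6st2 by 5.97 ± 0.46, and Edil3 by 5.24 ± 0.71. The calcineurin regulator gene Rcan2 was at least 55.3-fold lower and the transcription factor gene Sp8 at least 25-fold lower, both with 0 counts in the sgUhrf1 group. Count ratios were 130-fold lower for Rims2 (interval 22.9 to 5155), 105-fold for the basement membrane collagen gene Col4a6 (18.5 to 4180), 73.2-fold for Lrch2 (12.8 to 2926) and 34.7-fold for the sodium channel gene Nalcn (11.6 to 171). The rows of Rims2, Col4a6, Hs6st2 and Lrch2 covered only 142, 91, 91 and 63 bp of exon, and those of the other genes among these 10 at least 248 bp. Without sgNT replicate 2, the rows lower in sgUhrf1 tumours numbered 1259 and the genes named by position 613. Without sgNT replicate 2 and sgUhrf1 replicate 1, which held the most skeletal muscle reads, 1094 rows were higher and 771 lower, and 522 and 384 genes.

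Genes of MHC class I antigen presentation rose together. H2-K1, which encodes the classical class I heavy chain (chromosome 17, 33996017 to 34000347, minus strand), went from 1505 ± 799 to 13576 ± 2766 CPM, a 9.02-fold rise (log2 3.17 ± 0.42 SE, n = 3 per group). Psmb9 and Psmb8, immunoproteasome subunits, rose by 3.87 ± 0.51 and 3.82 ± 0.50 on the log2 scale, the peptide transporter gene Tap2 by 3.57 ± 0.31, and Nlrc5, the class I transactivator, by 2.60 ± 0.46. Of 17 genes in the list, 7 were tested, 6 were higher and 1, the peptide-trimming gene Erap1, was not past the threshold at -1.06 ± 0.40. Adjusted over the list alone, Erap1 counted as lower. The list's median was 3.17, with a camera adjusted p of 0.00758 and an adjusted p = 0.448 with an estimated correlation. Counting shared rows too, 11 of 14 were higher, with a median of 2.39. Non-classical class I genes rose too, 5 of 5 tested: H2-Q7 by 4.55 ± 0.43, H2-Q4 by 4.04 ± 0.43, H2-M2 by 4.78 ± 0.53, and H2-Q2 from 1 to 314 counts (356-fold, interval 63.4 to 14107). Their camera adjusted p was 0.000840, with an adjusted p = 0.448 with an estimated correlation. H2 genes are close copies, and reads may be split between them.

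**Figure D2:**
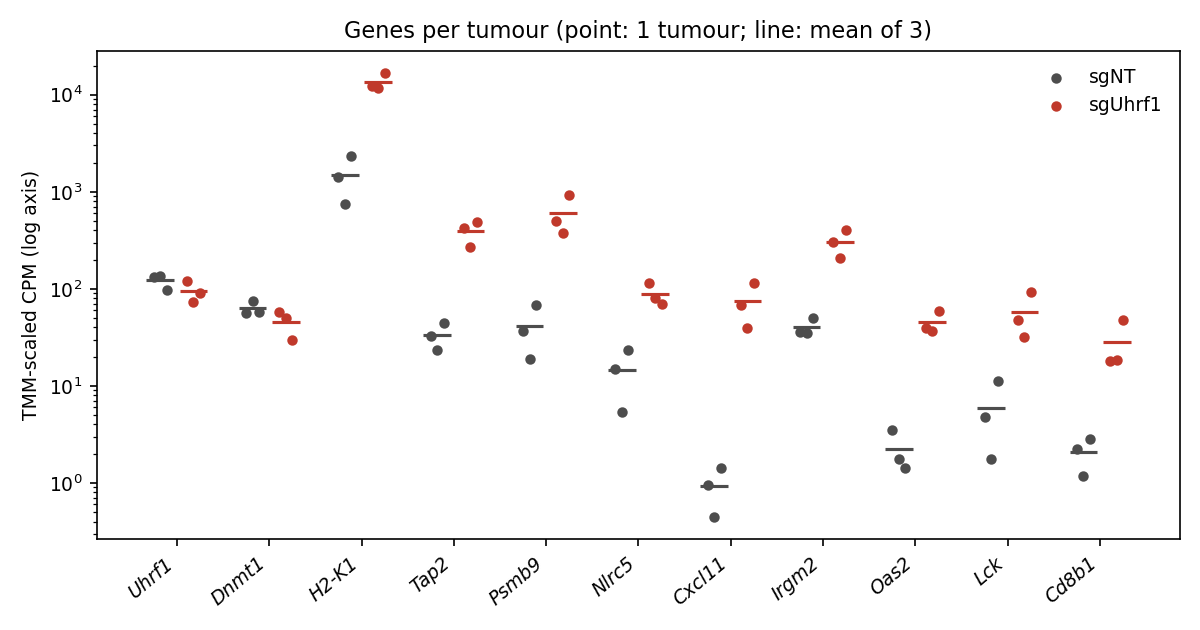
TMM-scaled CPM (log axis) of 11 genes in each tumour, sgNT in grey and sgUhrf1 in red; points are tumours and lines are means of 3. H2-K1, Tap2, Psmb9, Nlrc5, Cxcl11, Irgm2, Oas2, Lck and Cd8b1 lie higher in each sgUhrf1 tumour than in any sgNT tumour, while the groups overlap for the most counted row of Uhrf1 and for Dnmt1.

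Several core genes lie in rows shared with neighbours, and their rows rose as a whole. The row over H2-D1 and the RNA helicase gene Ddx39b rose by 1.73 ± 0.28 on the log2 scale, the row over Tap1 and Psmb8 by 3.49 ± 0.41, and the row over the chemokine genes Cxcl9 and Cxcl10 with Sdad1 and Art3 by 3.52 ± 0.31. The row over Cd8a and Rmnd5a rose by 0.83 ± 0.22. Each of these had an edgeR adjusted p between 0.000148 and 0.0174, and the share of each gene in its row is unknown. No tested row covered B2m, Cd274, Ifng, Cd3e, Gzmb, Prf1 or Pdcd1, which were not analysed here.

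Interferon-gamma response genes were higher in 6 of 6 tested from a list of 20. Cxcl11, a chemokine gene that the annotation lists as a polymorphic pseudogene, went from 0.938 ± 0.487 to 74.2 ± 38.0 CPM (log2 6.30 ± 0.53 SE, n = 3 per group). The immunity-related GTPase gene Irgm2 rose by 2.92 ± 0.28, the guanylate-binding protein gene Gbp6 by 3.77 ± 0.47, and the transcription factor gene Irf8 by 1.80 ± 0.31. The list's median was 3.64 (camera adjusted p = 0.00106; adjusted p = 0.448 with an estimated correlation). The type I interferon list had 4 tested of 23 and all 4 rose: the antiviral synthetase gene Oas3 from 2.38 ± 0.454 to 38.4 ± 13.5 CPM, Oas2 and Oasl2 by 4.32 ± 0.39 and 4.44 ± 0.46, and the RNA sensor gene Ddx58 by 1.39 ± 0.27. Its median was 4.16 (camera adjusted p = 0.00385; adjusted p = 0.448 with an estimated correlation).

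T cell genes were higher in sgUhrf1 tumours. The T cell signalling genes Lat, Lck and Zap70 rose by 2.70 ± 0.40, 3.29 ± 0.62 and 2.95 ± 0.54 on the log2 scale (SE, n = 3 per group), 3 of 3 tested from a list of 18. Cd8b1, the CD8 beta chain, went from 2.08 ± 0.833 to 28.2 ± 16.9 CPM (3.76 ± 0.51), the cytotoxic lymphocyte protease gene Ctsw rose by 4.03 ± 0.69 and the NK and T cell receptor gene Klrd1 by 2.69 ± 0.49, 3 of 3 tested from a list of 16. The rows of Cd8b1 and Ctsw covered only 127 and 138 bp of exon, and those of Lat, Lck, Zap70 and Klrd1 at least 204 bp. The medians were 2.95 and 3.76, with camera adjusted p of 0.0311 for T cells and 0.0227 for CD8 T cells and cytotoxicity, and an adjusted p = 0.448 with an estimated correlation for both. With shared rows counted, 7 of 7 T cell rows were higher (median 2.91) and 6 of 8 CD8 rows (median 2.24, adjusted p = 0.00321). In the regulatory T cell list 3 of 4 rose, Ikzf4 by 2.86 ± 0.44, Ikzf2 by 1.74 ± 0.33 and the costimulatory receptor gene Tnfrsf4 by 2.76 ± 0.59 (median 2.25, camera adjusted p = 0.0384; adjusted p = 0.448 with an estimated correlation), and that call was lost without sgNT replicate 1, sgUhrf1 replicate 1 or sgUhrf1 replicate 2 (adjusted p of at most 0.0624) and with at least 200 bp of exon overlap (median 1.74, adjusted p = 0.127). Of the T cell checkpoint list 0 of 3 passed in edgeR; Tnfrsf9 was at -0.80 ± 0.47 and Havcr2 at -0.22 ± 0.33, and Tnfrsf9 passed without sgUhrf1 replicate 3 (-1.38, adjusted p = 0.0460). Among checkpoint rows including shared ones, 2 of 6 were higher (median -0.14, adjusted p = 0.801), singled out after their values were seen: the row over Tox and Gm11802 by 2.86 ± 0.57 and the row over Lag3 and Ptms by 1.00 ± 0.22.

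Myeloid genes did not move as 1 group. Of 6 monocyte and macrophage genes 0 passed. The complement gene C1qc had a log2 fold change of 0.72 ± 0.38 and Trem2 of 1.07 ± 0.57. The list's median of -0.31, mean of 0.0054 and test direction differed in sign (camera adjusted p = 0.928). Its median ran from -0.65 to 0.053 when single tumours were left out. Among dendritic cell genes the chemokine gene Ccl22 and the integrin gene Itgax rose, by 3.68 ± 0.38 and 2.15 ± 0.29 on the log2 scale. Wdfy4, needed for cross-presentation, fell by 1.89 ± 0.57 (SE, n = 3 per group). The dendritic cell list had a camera adjusted p of 0.338 but passed with fry (adjusted p = 0.00804). The fall of Wdfy4 was lost without sgNT replicate 2 or 3 or without sgUhrf1 replicate 2 or 3 (adjusted p = 0.0607 to 0.140), with the block, with limma-voom and without the muscle-rich tumours; C1qc passed without sgUhrf1 replicate 2 (1.07, adjusted p = 0.00819). The neutrophil list had 2 tested genes, of which the growth factor receptor gene Csf3r rose by 3.46 ± 0.35. Shared rows brought the list to 5 of 7 higher and 1 lower, and it passed (median 2.71, adjusted p = 0.0246). In MHC class II presentation 3 of 6 rose, H2-DMb1 by 3.39 ± 0.35, H2-Eb1 by 2.74 ± 0.37 and H2-DMa by 2.16 ± 0.30, with a median of 1.33 (camera adjusted p = 0.101; adjusted p = 0.760 with an estimated correlation), a list that passed without sgNT replicate 3 (adjusted p = 0.00832) and with shared rows counted (5 of 11 higher, median 0.56, adjusted p = 0.0341).

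In the lung epithelial list 4 of 5 tested genes rose in sgUhrf1 tumours, and 5 of 7 mesenchymal transition genes fell. In the lung list the surfactant protein gene Sftpd rose from 0.359 ± 0.331 to 43.4 ± 30.4 CPM (log2 6.79 ± 0.90 SE, n = 3 per group), the keratin gene Krt7 by 3.55 ± 0.66, E-cadherin (Cdh1) by 2.53 ± 0.29 and the transcription factor gene Hnf4a by 3.32 ± 0.82. The other surfactant protein gene tested, Sftpb, did not pass at 0.80 ± 0.53. Krt7 and Cdh1 are shared by many epithelia, and Hnf4a is better known from liver and gut than from lung. Hnf4a missed the threshold in the robust fit (adjusted p = 0.0608) and without the 2 muscle-rich tumours (0.0530). The list's median was 3.32 (camera adjusted p = 0.0154; adjusted p = 0.448 with an estimated correlation). Once shared rows were counted, 7 of 16 rows were higher and the median was 0.97 (adjusted p = 0.0116). Of the mesenchymal genes, Tgfbi fell by 1.99 ± 0.28, Hmga2 by 2.20 ± 0.48, Itga5 by 1.18 ± 0.21 and Zeb2 by 1.43 ± 0.37. The rows of Tgfbi and Itga5 covered only 57 and 149 bp of exon, and those of Hmga2 and Zeb2 1329 and 3875 bp. As a list the 7 missed the threshold (median -1.18, camera adjusted p = 0.0514, from 0.0318 to 0.269 over 18 alternatives, and 0.570 with an estimated correlation). It passed in 10 of the 18: with median-of-ratios factors, no filter, the stricter filter, the replicate block, fry, shared rows or summed rows, and without sgNT replicate 1, sgNT replicate 3 or sgUhrf1 replicate 3. Of 9 fibroblast and matrix genes 3 fell, fibronectin (Fn1) by 2.11 ± 0.37, Col5a1 by 1.76 ± 0.39 and Pdgfra by 1.73 ± 0.49 (median -0.21, camera adjusted p = 0.305). That median ran from -0.41 to 0.051 when single tumours were left out. The list passed with shared rows counted (9 of 18 rows lower, median -1.25, adjusted p = 0.00749). Without sgNT replicate 2, Zeb2 and Pdgfra missed the threshold (adjusted p = 0.0552 and 0.0736), and Vwf passed without sgNT replicate 1 (-1.51, adjusted p = 0.0171). Of 5 endothelial genes 0 passed in edgeR (2 at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma-voom), with Vwf at -1.16 ± 0.43 and Pecam1 at 0.82 ± 0.36 (1.10 without sgUhrf1 replicate 2, adjusted p = 0.0221); the list's median of 0.091 and mean of -0.029 differed in sign (camera adjusted p = 0.928). With shared rows 2 of 15 were higher (median 0.35, adjusted p = 0.627).

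**Figure D3:**
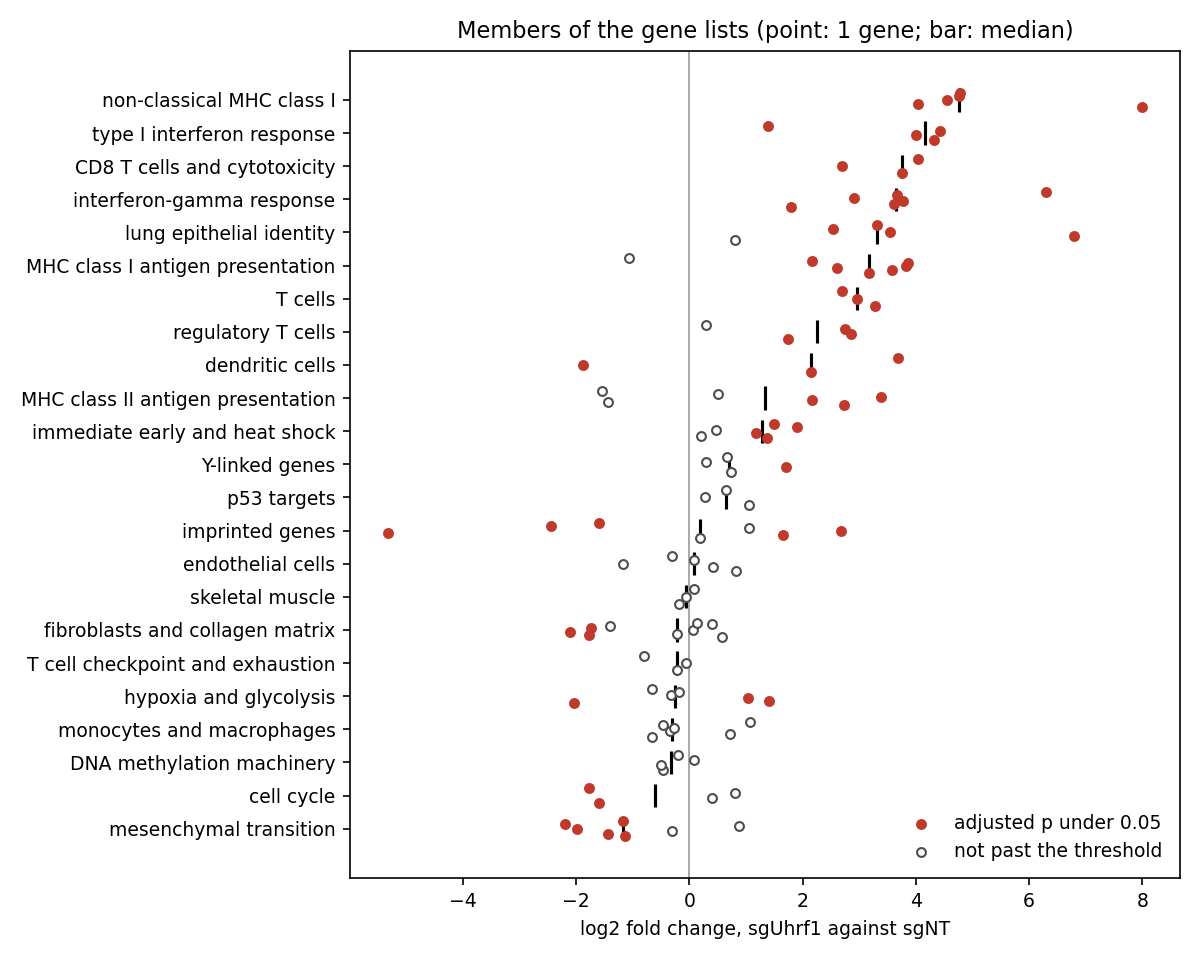
Log2 fold change (sgUhrf1 against sgNT) of each tested member of the 23 lists with at least 3 tested genes; filled points passed an adjusted p of 0.05, open points did not, and bars are list medians. Both MHC class I lists, both interferon lists and both T cell effector lists have medians above 2.9, while monocyte and macrophage genes centre on -0.31.

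Cell division and DNA methylation genes did not move as lists. Mcm2 and E2f1 fell by 1.60 ± 0.33 and 1.77 ± 0.41 (SE, n = 3 per group), 2 of 4 cell cycle genes tested (camera adjusted p = 0.652). Adjusted over the list alone, 1 member counted as higher. Of 4 genes of the DNA methylation machinery 0 passed in edgeR, with Dnmt3a at -0.50 ± 0.24 (median -0.33, camera adjusted p = 0.596). With shared rows 1 of 16 was higher and 1 lower (median -0.064). In the checkpoint, macrophage, skeletal muscle and DNA methylation lists 0 genes with a row of their own reached even an unadjusted p of 0.05 in edgeR, and DESeq2 and limma-voom also passed 0. Apart from the MHC class I, cell cycle, p53 target and hypoxia and glycolysis lists, counts adjusted over the list alone were equal to those over all rows.

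Y-linked genes, which female hosts lack, were present in all tumours and stand at the same place in both builds. Eif2s3y rose from 20.3 ± 10.1 to 65.9 ± 30.5 CPM (log2 1.70 ± 0.45 SE, n = 3 per group, edgeR adjusted p = 0.0157), a call that was lost without sgUhrf1 replicate 3 (adjusted p = 0.0534). Ddx3y, Uty and Kdm5d had log2 fold changes of 0.73 ± 0.40, 0.66 ± 0.44 and 0.29 ± 0.33 and did not pass, but Ddx3y passed without sgUhrf1 replicate 2 (1.09, adjusted p = 0.0167). The list's median was 0.70 (camera adjusted p = 0.360). Ddx3y ranged from 29.6 to 40.2 CPM in sgNT tumours and from 25.1 to 94.6 CPM in sgUhrf1 tumours.

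The shares of mitochondrial and ribosomal RNA overlapped between groups. Mitochondrial rows took 5.58% to 8.29% of counts in sgNT and 7.71% to 9.05% in sgUhrf1 tumours, ribosomal RNA 0.626% to 1.59% and 0.380% to 2.13%. The 10 most counted rows took 11.0% to 13.7% in sgNT and 13.8% to 17.6% in sgUhrf1 tumours. Creatine kinase (Ckm), a skeletal muscle gene, stood at 243 CPM in sgNT replicate 2 and 186 CPM in sgUhrf1 replicate 1, and between 0.177 and 18 CPM in the other tumours. Of 3 skeletal muscle genes 0 passed in edgeR, with Ckm at -0.19 ± 1.61 and Ryr1 at 0.087 ± 1.00 (camera adjusted p = 0.766).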

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

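The deposited row names, shared rows, 200 bp overlap, summed counts and the runs without muscle-rich tumours or without mitochondrial and ribosomal RNA were tried after seeing the data. Of 4187 changed rows, none reversed while past the threshold under any of the 17 refits, and from 1794 to 4187 kept their call. Rows higher numbered from 1431 to 2020 and lower from 1259 to 1908 when single tumours were left out; for genes named by position these ranges were 657 to 921 and 613 to 902. Without the 2 tumours richest in muscle reads, 1094 rows were higher and 771 lower, and 522 and 384 genes, with fewer samples tested; 1794 of these rows were among the 4187, and Lor, Mcm2, Meg3, Dusp1, Hk2, Hnf4a, Zeb2, Eif2s3y, Pdgfra, Peg13, Nr4a1 and Wdfy4 missed the threshold. Ckm then stood at 3.49, and it ranged from -2.47 to 5.73 when single tumours were left out. Library totals gave 1630 higher and 2268 lower. The replicate numbers did not pair the tumours: deviations of same-numbered tumours correlated at -0.079, -0.021 and 0.050, and not every tumour correlated best with its own number. With the replicate number as a block, 1838 rows were higher and 1807 lower, and Peg13, Nr4a1 and Wdfy4 were no longer past the threshold. With an estimated correlation 0 of 23 lists passed instead of 9, and 0 had an unadjusted p under 0.05; this setting cannot move the medians (MHC class I 3.17, interferon-gamma 3.64, CD8 3.76), and these 3 lists had an adjusted p of 0.448. With fry 11 lists passed. With shared rows counted, more members entered and 14 lists passed, among them the fibroblast list, while the immediate early list did not. With at least 200 bp of exon overlap 6 lists passed; the regulatory T cell and immediate early lists were lost, and the CD8 list had too few members. The most counted row of Uhrf1, or the sum of its rows, stayed short of the threshold in all 18 alternatives that keep the naming by position, from -0.60 to -0.22. Read by the deposited names, which mostly hold other genes' reads, 1 list passed; MHC class I had a median of -0.046 and interferon-gamma of 0.27 (adjusted p = 0.871), the CD8 list had too few members, and rows named Dnmt1 (2.99), Wdfy4 (1.14), Prss32 (-1.06), Ikzf4 (-0.90), Zap70 (-0.87), Ccl22 (-0.83), Dusp1 (-0.77), Xdh (-0.65), Irgm2 (-0.61), Hnf4a (-0.28), Cdh1 (-0.25) and Oit1 (-0.024) had the opposite sign. In the simulation, with 200 changed rows, 15.1% of 2-fold changes were recovered; with 4187 rows changed the same adjusted p is easier to reach, and 3166 of these changed by 2-fold or more, so the simulated share does not carry over to these data.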

Other observations

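Imprinted genes changed in both directions. Besides Peg10, the growth factor receptor gene Igf2r fell by 2.44 ± 0.27 on the log2 scale (SE, n = 3 per group), while the maternally expressed RNA Meg3 rose by 2.67 ± 0.60. Of 7 tested, 2 rose and 3 fell. The median of 0.19 and the mean of -0.54 differed in sign (camera adjusted p = 0.596), and the median ran from -0.57 to 0.70 when single tumours were left out. Of germline genes silenced by DNA methylation, 2 were tested: Asz1 rose from 0.775 ± 0.792 to 19.3 ± 8.75 CPM (4.57 ± 0.72) and Dpep3 fell by 3.81 ± 0.70. The list was too short for a test.

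Immediate early genes were higher, 4 of 6 tested. On the log2 scale Btg2 rose by 1.49 ± 0.25 (SE), Fos by 1.37 ± 0.31, Dusp1 by 1.18 ± 0.28 and the nuclear receptor gene Nr4a1 by 1.90 ± 0.57. The list's median was 1.28, and it passed with a camera adjusted p of 0.0384 (0.448 with an estimated correlation). That call was lost without sgNT replicate 1, sgNT replicate 2 or sgUhrf1 replicate 2, at an adjusted p of at most 0.0911, with at least 200 bp of exon overlap (0.101) and with shared rows counted (6 of 11 higher, median 0.56, adjusted p = 0.0501); Nr4a1 missed the threshold without sgNT replicate 2 or 3 or sgUhrf1 replicate 3 (adjusted p = 0.0832 to 0.105). In the hypoxia and glycolysis list Adm and Hk2 rose, by 2.64-fold and 2.05-fold, and Pdk1 fell 4.11-fold (log2 -2.04 ± 0.33). The list had 6 tested genes and a camera adjusted p of 0.896. Adjusted over the list alone, 2 counted as lower. Hk2 missed the threshold without sgNT replicate 2 (adjusted p = 0.0570), without the 2 muscle-rich tumours (0.0600) and with rows summed per gene (log2 0.66, adjusted p = 0.0545). Of 3 p53 targets 0 passed in edgeR over all rows (2 at an unadjusted p under 0.05, 2 in DESeq2, 0 in limma-voom). Adjusted over the list alone 2 rose, with log2 fold changes of 0.64 ± 0.23 for Bax and 1.05 ± 0.40 for Cdkn1a. The list's camera adjusted p was 0.360. Both genes passed without sgUhrf1 replicate 2 (adjusted p = 0.0392 and 0.0341), and Bax without sgUhrf1 replicate 1 (0.0456). Single tested members stood for 5 further lists. On the log2 scale the chemokine gene Cx3cl1 rose by 1.16 ± 0.25, the mammary gene Xdh by 2.27 ± 0.34, and the keratinocyte gene Lor fell by 1.31 ± 0.25. The B cell gene Blk (log2 0.98 ± 1.00) and the adipocyte gene Retn (log2 0.95 ± 0.82) did not pass. Blk did pass without sgNT replicate 3 (adjusted p = 0.00580) and in limma-voom (0.0487). Lor missed the threshold without the 2 muscle-rich tumours (0.0571). NK cell genes had 0 tested members with a row of their own. With shared rows counted, the chemokine list (3 of 3 higher, median 3.00, adjusted p = 0.0218) and the mammary list (3 of 3, median 1.99, 0.0246) passed, and the NK cell (3 of 4 higher and 1 lower), keratinocyte (2 of 3 higher and 1 lower), adipocyte (3 of 9 higher) and B cell (0 of 4) lists did not (adjusted p = 0.372, 0.521, 0.125 and 0.801). The chemokine and mammary lists each had only 1 tested member with a row of its own. How much of the rise in their other rows belongs to neighbouring genes is unknown.

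The tests of the leukocyte share, scaling, MHC copies, cell lines, chromosome majorities and other groupings of the tumours were chosen only after the values were seen. The rise of MHC class I and interferon genes was set against technical explanations. A larger share of leukocytes as a whole would raise pan-leukocyte genes alike, yet 15 tested ones, with Ptprc at 0.30 ± 0.36, had a median of 0.30 and a mean of 0.31 ± 0.26 (SE over genes), against a bound of 1.59, set at 0.5 of the MHC class I median; 3 of them rose, Vav1, Plek and Ctss. Library scaling left the MHC class I median at no less than 3.00, and the 6 members outside the H2 family had a median of 3.09, so reads shared between H2 copies do not account for those. A larger share of T cells, whose genes rose, stays open. For a single H2 gene, reads passing from other H2 genes stay open too. Passing alone, with no H2 gene truly higher, would need an H2 row that fell. Counting shared rows, 9 of 9 non-classical rows were higher, and in the MHC class I list 11 of 14 were higher and 0 lower. These values argue against it for the tested rows as a set. With 1 cell line per group, an effect of the guide and other differences between the 2 lines cannot be told apart.

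The rise of gastrointestinal epithelial genes was followed in a list that left out the genes already seen. Of 60 such genes 9 were tested and 7 rose, among them Cdh17 by 3.58 ± 0.31, Vil1 by 4.22 ± 0.62 and Lgals4 by 4.63 ± 0.87 (median 3.53, camera p = 9.9e-05; p = 0.0920 with an estimated correlation). Rows named for wrong genes would not be expected to rise as such a list. Their mean lay above every sgNT tumour in 3 of 3 sgUhrf1 tumours, so the rise was not confined to 1 tumour. This adds little to what was already seen, because the genes that prompted the list were chosen for no overlap between groups in the same tumours. With 1 line per group, an effect of the guide cannot be told apart from a difference between the lines that has nothing to do with Uhrf1, and which cells carried the rise was not tested.

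Changed genes lay on every chromosome with at least 20 tested genes, and of these 20 chromosomes 5 had a median above that of all genes and 4 below, by a 95% bootstrap interval over genes. Genes on chromosome X had a median log2 fold change 0.70 below that of all genes (-1.01 to -0.50 over 113 genes), with 11 higher and 49 lower, and those on chromosome 2 lay 0.36 below (-0.51 to -0.20 over 336 genes). Chromosomes 7, 17 and 6 lay 0.29 (0.18 to 0.43), 0.29 (0.12 to 0.46) and 0.27 (0.14 to 0.38) above, and chromosome 10 lay 0.27 below (-0.42 to -0.11). Chromosomes X and 2, over 0.3 away, held 10.9% of the changed genes and 9.81% of all tested genes, so the bound of 10% set beforehand could not decide, and a gain or loss of whole chromosomes in 1 line may add to the changes and stays open. As the direct cause of all changes it would move the genes of a chromosome 1 way. Yet over the 20 chromosomes 39.5% of changed genes moved against the majority of their chromosome (95% bootstrap interval over chromosomes 35.9 to 42.8), from 18.3% on chromosome X to 49.3% on chromosome 8. This share does not bear on gains or losses of parts of chromosomes, or on indirect effects on other genes. The real grouping gave 4187 changed rows and the highest of the other 9 groupings gave 0 in edgeR, with at most 257 at an unadjusted p under 0.05. Each of those 9 sets 2 tumours of 1 group beside 1 of the other. The real difference then counts as spread within groups, so a low count was likely from the start and gives no baseline for chance. Of 10 groupings 1 reached the real count, and 10 are too few for a share under 0.05.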
